A study of Homo sapiens with 24 samples.

How the data were processed

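The samples were MCF-7 cells of 2 genotypes, WT and HIF1A-null, exposed for 6 h to DMSO, CoCl2, ciclopirox or wortmannin, with 3 libraries in each of the 8 groups. The group and the replicate number of each library were read from the labels. Per the growth protocol in the labels, treatments were repeated in at least 3 separate experiments on different cell batches, but the labels do not say that a replicate number marks a shared batch. The HIF1A-null cells were a single pool, so p-values measure the spread between these cultures and not between independently made knockouts.

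The deposited table held whole-number counts per detector probe and library, with no normalization, and each column was matched to 1 library by its name. Per the labels' protocols, RNA was extracted with Trizol and measured with a custom-attenuated human whole-transcriptome TempO-Seq panel. Attenuation lowers the signal of selected probes, so levels of different probes are not comparable and changes were tested as ratios of a probe between libraries. The share of counts in the 50 most counted probes and the choice of a gene's probe by its mean count rest on attenuated levels. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.9 and the GRCh38 build were used, and the counting step is not given in the sources used here. The table had 22533 probes for 19683 gene symbols, 2211 of them with 2 or more probes. Of the symbols, 19277 matched a current symbol and 406 did not, and symbols are printed as deposited. Each probe was tested on its own. Probes for genes with near-identical copies can take reads of a copy, and such genes are described as uncertain.

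Total counts ranged from 3842482 to 7464871 per library. Intervals given for shares cover counting error only. Of the 24 pairs of replicates within a group, 0 agreed within sampling noise, the chi-square per probe between replicates being 4.14 to 72.59 over probes with at least 20 counts in the pair.

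Tests used R 4.3.3. Probes were kept with edgeR's filterByExpr by group, which left 15246 probes for 13520 symbols, libraries were scaled with TMM factors, and all 24 libraries entered 1 model with a term per group. Contrasts were tested with edgeR 4.0.16's quasi-likelihood test, two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with 0.05 as the threshold. All adjusted p-values of single probes come from this test. A ± after a log2 change is a standard error, the size of the change divided by the square root of its F statistic, and a ± after a level in CPM (counts-per-million of the TMM-scaled library) is an SD over 3 libraries. The 10 contrasts were genotype in DMSO, each exposure against DMSO within each genotype, and the genotype by exposure interaction of each exposure. These contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparison of genotypes within CoCl2, ciclopirox and wortmannin, 3 contrasts that use no WT DMSO library, was added after seeing the data.

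The 26 gene lists covered HIF targets, glycolysis, metal and stress responses, growth and cell cycle programs, and markers of luminal, basal, fibroblast and blood cells. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, using the probe with the highest mean count of each gene. The p-values were adjusted over the 260 tests of the 10 contrasts, and over the 78 tests of the 3 added contrasts separately. Camera was run again with a correlation estimated per list, and the call counts of a list's members are given both over all probes and adjusted over the list alone. Genes could be named if they were among the 12 strongest changes in each direction of each of the 10 contrasts with a mean of at least 20 counts, and for contrasts of 2 groups with the groups not overlapping, or were members of the lists, or HIF1A. Not all of these are named, and the choice among them was made after their values were seen. Groups of 3 against 3 fail to overlap by chance in 10% of genes. Other genes are named as chosen after their values were seen.

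The alternatives tried were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, only the groups compared in the fit, probes summed per gene, the replicate number as a block, and each library left out in turn. For lists, the rotation test fry and all probes of a gene were also tried. Added after seeing the data were limma voom with sample weights, WT DMSO replicates 1 and 2 left out, all WT DMSO libraries left out of the fit where a contrast did not use them, and a library quality axis as a covariate. That axis was the first component of the deviations within groups other than WT DMSO, where it held 37.7% of the variance, with every library projected on it. Levels for plots were log2 CPM with a prior count of 2. With DESeq2 size factors the median log2 change of all probes moved by -0.05 to 0.07.

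The procedure was tested on simulated data for 15085 genes, with the libraries' own means and totals. For CoCl2 against DMSO in WT cells it recovered 1.5% of 67 genes changed 1.5-fold, 20.9% of 67 changed 2-fold and 66.7% of 66 changed 4-fold, with 6 false calls among 70 that also held 5 of a planted list of 44 genes changed 2-fold. For the CoCl2 interaction it recovered 4.5% of genes changed 2-fold and 48.5% of those changed 4-fold, with 4 false calls among 41, which held 1 of the list and 1 gene changed 1.5-fold. A comparison with no change planted gave 0 calls. Gene positions are from GENCODE 29 on GRCh38, counted from 1, and the exon a probe lies in is not given in the sources used here.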

Results

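The data were counts from TempO-Seq, a targeted RNA assay in which pairs of short detector probes are joined on their transcript and the joined products are counted by sequencing. The cells were MCF-7, an estrogen receptor-positive human breast adenocarcinoma line, either wild type (WT) or a HIF1A-null knockout pool that per the series description held at least 90% null cells. HIF1A encodes the oxygen-regulated subunit of hypoxia-inducible factor 1 (HIF-1). Both genotypes were exposed for 6 h to DMSO (0.01%), to CoCl2 (200 µM), a metal salt that mimics hypoxia, to ciclopirox (15 µM), an antifungal iron chelator, or to wortmannin (1 µM), an inhibitor of phosphoinositide 3-kinase. The 2 genotypes and 4 exposures gave 8 groups of 3 libraries, 24 in all. Total counts per library ranged from 3842482 to 7464871 with a median of 6671142.5, over 22533 probes for 19683 gene symbols, of which 15246 probes were tested.

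The HIF1A probe (HIF1A_2945) was counted in every group. Its level was 10.7 ± 7.87 CPM (counts-per-million) in WT DMSO libraries (SD, n = 3 here and below), 61.1 ± 7.80 in WT CoCl2, 59.1 ± 5.53 in WT ciclopirox and 66.9 ± 39.4 in WT wortmannin. In HIF1A-null libraries it was 32.4 ± 3.90 with DMSO, 44.4 ± 4.30 with CoCl2, 39.3 ± 17.5 with ciclopirox and 38.8 ± 5.21 with wortmannin. The transcript was therefore counted in both genotypes, and where the probe lies relative to the edit is not given in the sources used here, so its level checks nothing about the knockout. HIF1A lies on chromosome 14 from 61695513 to 61748259 on the plus strand of GRCh38 and is annotated as a protein-coding gene. The probe was higher in HIF1A-null than in WT cells with DMSO (log2 1.53 ± 0.42 SE, adjusted p = 0.00412, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With CoCl2, ciclopirox and wortmannin its differences of -0.46 ± 0.39, -0.58 ± 0.39 and -0.79 ± 0.39 did not pass. The difference in DMSO rests on the WT DMSO libraries, which stood apart from all others (next paragraph) and were below the other WT groups. The call in DMSO therefore does not by itself show raised HIF1A RNA in the knockout pool.

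The 3 WT DMSO libraries stood apart from the other 21. The first principal component held 51.9% of the variance, and their scores on it were -141.5, -171.3 and -99.8, against -54.7 to 76.5 elsewhere. In WT DMSO replicates 1, 2 and 3 the 50 most counted probes took 12.35%, 12.18% and 9.07% of all counts, against 6.81% to 8.25% in the other libraries. Their median correlations with libraries of other groups were 0.792, 0.786 and 0.884, against 0.923 to 0.959. The calmodulin gene CALM3 was at 676, 694 and 69.6 CPM in these libraries and at 14.6 ± 2.06 in HIF1A-null wortmannin libraries. ATL2, which encodes a GTPase that shapes the endoplasmic reticulum, was at 74.7, 41.8 and 3.34 CPM in WT DMSO and at 0.481 ± 0.118 in WT CoCl2. WT DMSO enters 4 of the 2-group comparisons, and 5746 probes were called in the same direction relative to WT DMSO in all 4.

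**Figure D1:**
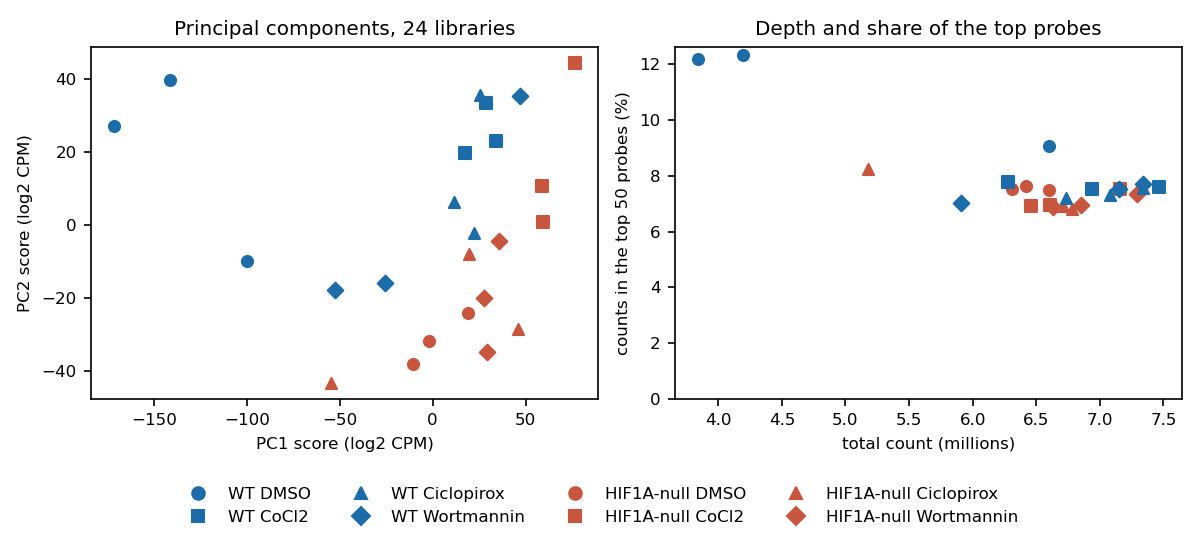
Left, scores of the 24 libraries on the first and second principal components of log2 CPM. Right, total count against the percentage of counts in the 50 most counted probes, 1 point per library, with colour for genotype and shape for exposure. The 3 WT DMSO libraries lie at scores of -99.8 or lower and at 9.07% or more.

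The genotypes were compared in DMSO, so these differences also hold the departure of the WT DMSO libraries. Of 14 measured luminal epithelial markers, genes of the secretory breast epithelium, 10 were lower in HIF1A-null cells and 0 higher (10 and 0 adjusted over the list alone), with a median log2 difference of -1.16. Between genotypes under CoCl2, ciclopirox and wortmannin, where far fewer probes were called, 0, 1 and 0 were lower over all probes. The list medians under ciclopirox and wortmannin were still negative. KRT19, a simple-epithelial keratin, was lower by -2.47 ± 0.35, from 355 ± 63.1 to 64.2 ± 6.35 CPM, and the tight-junction gene CLDN4 by -2.03 ± 0.29. TFF1, a secreted trefoil factor and an estrogen receptor target, was lower by -3.60 ± 0.39. Of 8 fibroblast markers, 5 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 0.101). Relative to HIF1A-null DMSO their median was -1.81, -1.15 and -0.97 in the WT DMSO libraries and between -1.63 and -0.82 in the other WT libraries. Of 26 genes of G2 and mitosis, 15 were higher and 4 lower (16 and 5 adjusted over the list alone). The HIF target list gave 11 higher and 10 lower among 44 members, with a median of 0.00, although CA9, a hypoxia-induced carbonic anhydrase, was lower by -4.56 ± 0.78, at 0.393 ± 0.444 against 9.78 ± 1.38 CPM. Without HIF1A-null DMSO replicate 1, 6 HIF targets were lower. In limma's camera test the luminal list passed (adjusted p = 0.00268, and adjusted p = 0.998 with an estimated correlation), as did the G2 and mitosis list (adjusted p = 0.0371, and adjusted p = 0.998 with an estimated correlation). The latter missed without HIF1A-null DMSO replicate 3 (adjusted p = 0.057) and without WT DMSO replicate 2. In total, edgeR called 7983 probes, 4101 higher and 3882 lower. With WT DMSO replicates 1 and 2 left out 2153 were called, and 4018 with the library quality axis as a covariate, both chosen after seeing the data.

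CoCl2 was compared with DMSO in WT cells to ask which genes the hypoxia mimetic changed. Of 44 HIF targets outside glycolysis, 31 rose and 4 fell (31 and 4 adjusted over the list alone), with a median log2 change of 1.89. EGLN3 and EGLN1, which encode prolyl hydroxylases that mark HIF subunits for degradation, rose by 4.12 ± 0.56 (probe EGLN3_88861) and 2.94 ± 0.26. BNIP3, a mitophagy receptor gene, rose by 3.98 ± 0.47. PFKFB4, a regulator of glycolytic flux, rose by 3.80 ± 0.27, from 5.61 ± 0.509 to 78.6 ± 8.56 CPM. It lies on chromosome 3 from 48517684 to 48562015 on the minus strand. SERPINE1, the gene of a plasminogen activator inhibitor, was among those that fell, by -2.49 ± 0.50. Without WT CoCl2 replicate 2 or without WT DMSO replicate 2, 2 HIF targets fell. Of 22 genes of glycolysis and glucose uptake, 12 rose and 0 fell (12 and 0 adjusted over the list alone). They included the pyruvate dehydrogenase kinase gene PDK1 (5.27 ± 0.72), the enolase ENO2 (3.69 ± 0.36), the hexokinase HK2 (3.37 ± 0.47) and the glucose transporter SLC2A3 (2.80 ± 0.33). In these comparisons the WT DMSO libraries held 9.07% to 12.35% of counts in 50 probes. The median of the HIF target list relative to HIF1A-null DMSO was 1.57, 1.55 and 1.33 in WT CoCl2 libraries and 0.12, 0.08 and 0.27 in WT wortmannin libraries. Camera called the HIF target list (adjusted p = 1.7e-10, and adjusted p = 0.254 with an estimated correlation) and the glycolysis list (adjusted p = 0.000366, and adjusted p = 0.605 with an estimated correlation). It also called G2 and mitosis, with 17 of 26 members higher and 4 lower (17 and 4 adjusted over the list alone, adjusted p = 0.00972, and adjusted p = 0.998 with an estimated correlation). In total, edgeR called 8874 probes, 4506 higher and 4368 lower. With WT DMSO replicates 1 and 2 left out 4912 were called, and 2151 with the library quality axis as a covariate, both chosen after seeing the data.

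CoCl2 was compared with DMSO in HIF1A-null cells, a pool of at least 90% null cells, to ask what changed where most cells lacked HIF1A. The share of cells that kept HIF1A was not measured here. Of 18 genes of the NRF2 oxidative stress response, 4 rose and 0 fell (7 and 1 adjusted over the list alone). The thioredoxin reductase TXNRD1 rose by 1.98 ± 0.35 and the quinone reductase NQO1 by 1.05 ± 0.21, from 451 ± 57.1 to 933 ± 81.5 CPM. Of 18 heat shock genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with the chaperone HSPA1B at 1.34 ± 0.22. HSPA1B has a near-identical copy, HSPA1A, so its count is uncertain. Of 24 immediate early genes, 0 rose and 7 fell (0 and 9 adjusted over the list alone). CCN2, a matricellular growth factor gene, fell by -2.54 ± 0.48 and IER3, a stress-induced survival gene, by -1.58 ± 0.35. Of 27 estrogen receptor targets, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with the trefoil factor TFF3 at 3.24 ± 0.72. HIF targets gave 6 higher and 2 lower of 44 (9 and 2 adjusted over the list alone), and BNIP3 rose from 23.9 ± 5.01 to 88.8 ± 12.8 CPM. The 6 became 1, 1 and 0 without HIF1A-null CoCl2 replicates 1, 2 and 3, and 3, 0 and 0 without HIF1A-null DMSO replicates 1, 2 and 3, while the 2 lower became 1 without HIF1A-null CoCl2 replicate 2 and 0 without its replicate 3 or HIF1A-null DMSO replicate 2 or 3. Of the strongest single changes, TGM2, a transglutaminase, fell by -3.43 ± 0.71 (probe TGM2_7066) and KRT6A, a stress keratin, by -3.33 ± 0.68. Camera called the lists for NRF2 (adjusted p = 0.00194), heat shock (adjusted p = 0.0144), immediate early genes (adjusted p = 0.000859) and estrogen receptor targets (adjusted p = 0.0348). With an estimated correlation none passed (adjusted p = 0.399, 0.73, 0.485 and 0.998 in that order). The heat shock call was lost without HIF1A-null CoCl2 replicate 3 (adjusted p = 0.102) and without HIF1A-null DMSO replicate 1, and the estrogen receptor call without HIF1A-null CoCl2 replicate 3 (adjusted p = 0.202) and without HIF1A-null DMSO replicate 3. In total, edgeR called 1669 probes, 828 higher and 841 lower. This count fell to 0 without HIF1A-null CoCl2 replicate 3, 0 without HIF1A-null DMSO replicate 2, 24 without HIF1A-null DMSO replicate 3, 323 without HIF1A-null CoCl2 replicate 2 and 741 without HIF1A-null DMSO replicate 1. No gene named in this paragraph passed without HIF1A-null CoCl2 replicate 3, HIF1A-null DMSO replicate 2 or HIF1A-null DMSO replicate 3, and IER3 also did not pass without HIF1A-null CoCl2 replicate 2. Without HIF1A-null CoCl2 replicate 3, HIF1A-null DMSO replicate 2 or HIF1A-null DMSO replicate 3, 0 members of the NRF2, heat shock, immediate early and estrogen receptor lists passed. Without HIF1A-null CoCl2 replicate 2, 2 heat shock genes and 2 estrogen receptor targets rose and 3 immediate early genes fell, and without HIF1A-null DMSO replicate 1, 2 heat shock genes and 3 estrogen receptor targets rose. In both cases 0 heat shock genes fell. DESeq2 called 2970 probes, and 4672 were called with only the compared groups in the fit. Voom with sample weights called 7226 and the quality axis as a covariate left 0, both chosen after seeing the data.

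The genotypes were compared under CoCl2 in a planned interaction and in a direct comparison added after seeing the data, which uses no WT DMSO library. In the direct comparison 21 of 44 HIF targets were lower in HIF1A-null cells and 0 higher (33 and 0 adjusted over the list alone), with a median log2 difference of -1.31. PFKFB4 was lower by -3.31 ± 0.25, at 7.91 ± 1.56 against 78.6 ± 8.56 CPM. NDRG1 (probe NDRG1_21187), a hypoxia- and stress-induced gene, was lower by -2.67 ± 0.38, CA9 by -4.33 ± 0.68 and BNIP3 by -2.16 ± 0.43. Of 22 glycolysis genes, 9 were lower and 0 higher (18 and 0 adjusted over the list alone), among them HK2 at -2.65 ± 0.46 and ENO2 at -1.83 ± 0.33. Both lists passed camera with a preset and with an estimated correlation (HIF targets adjusted p = 4.61e-39 and, with an estimated correlation, adjusted p = 0.000499, glycolysis adjusted p = 2.05e-19 and, with an estimated correlation, adjusted p = 0.00467). Without HIF1A-null CoCl2 replicate 3 the called HIF targets numbered 10 and the glycolysis genes 3, and the glycolysis genes numbered 5 without HIF1A-null CoCl2 replicate 1, WT CoCl2 replicate 1 or WT CoCl2 replicate 3. In the interaction, 20 of 44 HIF targets rose less or fell in HIF1A-null cells and 0 the reverse (25 and 0 adjusted over the list alone), with PFKFB4 at -3.23 ± 0.37 (camera adjusted p = 1.11e-12, and adjusted p = 0.223 with an estimated correlation). By edgeR's quasi-likelihood test, 292 probes differed between genotypes under CoCl2, 90 higher and 202 lower in HIF1A-null cells. Without HIF1A-null CoCl2 replicates 1, 2 and 3 in turn the count was 165, 184 and 86, and without WT CoCl2 replicates 1, 2 and 3 it was 104, 118 and 110. DESeq2 called 687 (318 higher and 369 lower), the fit of only the compared groups 2160 (1121 and 1039) and voom with sample weights 4017 (2145 and 1872), so the higher share of lower calls did not hold in the latter pair. In the CoCl2 interaction 49.9% of calls were higher with TMM factors and 55.5% with DESeq2 size factors, so the even split depended on scaling. The interaction called 2832 probes, 1413 higher and 1419 lower, 4734 by voom and 39 with WT DMSO replicates 1 and 2 left out. It called 1676 without WT DMSO replicate 2, 4762 without WT DMSO replicate 3, 1710 without HIF1A-null DMSO replicate 1 and 1759 without WT CoCl2 replicate 2.

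**Figure D2:**
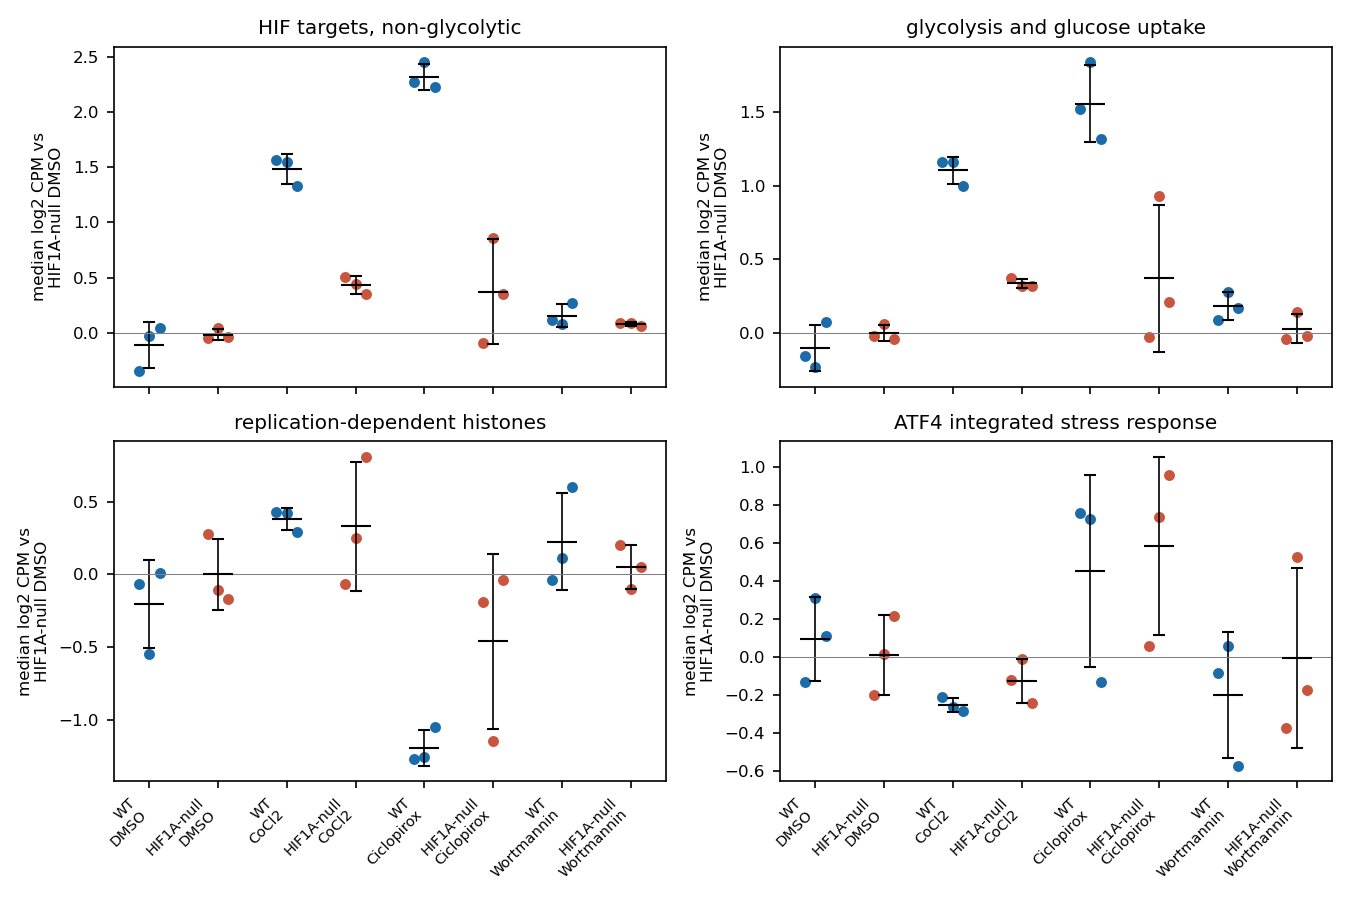
Median log2 CPM over the members of 4 gene lists, relative to the mean of the HIF1A-null DMSO libraries, by group. Coloured points are libraries and black marks give the mean ± SD of 3 libraries. The HIF target median lies between 2.23 and 2.45 in WT ciclopirox libraries and between -0.09 and 0.86 in HIF1A-null ciclopirox libraries.

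Ciclopirox was compared with DMSO in WT cells to ask what an iron chelator changed. Of the 44 HIF targets, 36 rose and 0 fell (36 and 1 adjusted over the list alone, and 1 fell without WT ciclopirox replicate 1), with a median log2 change of 2.86. EGLN3 (probe EGLN3_88861) rose by 6.10 ± 0.61, from 10.3 ± 3.73 to 705 ± 74.4 CPM. It lies on chromosome 14 from 33924231 to 34462774 on the minus strand. PPP1R3C, which directs a phosphatase to glycogen, rose by 5.52 ± 0.55, ANKRD37, an ankyrin repeat gene, by 5.12 ± 0.67, and the angiogenic factor VEGFA by 3.98 ± 0.47. Of 22 glycolysis genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone), with PDK1 at 6.01 ± 0.73, HK2 at 4.58 ± 0.50 and the aldolase ALDOC at 4.22 ± 0.42. Of 16 histone genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone, and 1 rose without WT DMSO replicate 3), with a median of -1.25. H1-4, a linker histone, fell by -3.43 ± 0.36, from 5670 ± 2540 to 524 ± 5.25 CPM, and the core histone gene H3C2 by -3.49 ± 0.40. The histone genes have near-identical copies, so counts of single members are uncertain, and 1 member, H1-0, belongs to the histones made outside replication. Of 8 metal response genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a list median relative to HIF1A-null DMSO of 1.72, 1.92 and 0.31 in WT ciclopirox replicates 1, 2 and 3, and with the metallothioneins MT2A at 1.46 ± 0.33 and MT1X at 3.09 ± 0.70, the latter one of a family of close copies and also uncertain. Camera called HIF targets (adjusted p = 1.53e-18, and adjusted p = 0.17 with an estimated correlation), glycolysis (adjusted p = 1.06e-07, and adjusted p = 0.268 with an estimated correlation) and histones (adjusted p = 0.00048, and adjusted p = 0.62 with an estimated correlation), but not the metal response (adjusted p = 0.123). In these comparisons too the WT DMSO libraries held 9.07% to 12.35% of counts in 50 probes, and relative to HIF1A-null DMSO the histone median was -1.27, -1.26 and -1.05 in WT ciclopirox libraries. In total, edgeR called 8740 probes, 4565 higher and 4175 lower. With WT DMSO replicates 1 and 2 left out 4394 were called, and 2719 with the library quality axis as a covariate.

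In HIF1A-null cells ciclopirox changed 0 probes relative to DMSO by edgeR's quasi-likelihood test, while 264 had an unadjusted p below 0.05, DESeq2 called 0 and limma voom with sample weights 57. Without HIF1A-null ciclopirox replicate 1, edgeR called 4, of which 1 was a HIF target and 1 an ATF4 list member, and both rose. Of the lists tested with camera at the preset correlation, 13 passed, all of which were lost with fry. In 1 of them 26 of 27 genes of the ATF4 stress response had positive log2 values, with a median of 0.61 (camera adjusted p = 2.85e-17, and adjusted p = 0.254 with an estimated correlation). Adjusted over the list alone, 1 of them passed and over all genes 0, and the library medians relative to HIF1A-null DMSO were 0.06, 0.74 and 0.96 in replicates 1, 2 and 3. HIF targets had a median of 0.43 with 39 of 44 positive (0 passing over all genes, 6 higher and 0 lower adjusted over the list alone, camera adjusted p = 6.21e-12, and adjusted p = 0.254 with an estimated correlation). This list call was lost without HIF1A-null ciclopirox replicate 2 (adjusted p = 0.0971). The histone median was -0.33, with 0 of 16 passing over all genes and 0 adjusted over the list alone (camera adjusted p = 1.95e-06, and adjusted p = 0.378 with an estimated correlation), and that call was also lost without HIF1A-null ciclopirox replicate 2 (adjusted p = 0.172). The 3 libraries of this group differed, with EGLN3 (probe EGLN3_88861) at 7.78, 85.2 and 13.7 and H1-4 at 2320, 574 and 2250 CPM in replicates 1, 2 and 3. They also differed in total counts (5177389, 6708080 and 6784392) and in the share of the 50 most counted probes (8.25%, 6.93% and 6.81%).

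Between the genotypes under ciclopirox, compared directly as an addition made after seeing the data, 27 of 44 HIF targets were lower in HIF1A-null cells and 0 higher (35 and 0 adjusted over the list alone), with a median of -1.70. PFKFB4 was lower by -3.91 ± 0.26, at 9.19 ± 4.00 against 138 ± 13.0 CPM, EGLN3 by -4.30 ± 0.54 (probe EGLN3_88861), CA9 by -6.08 ± 0.71 and NDRG1 by -3.24 ± 0.39 (probe NDRG1_21187). NDRG1 lies on chromosome 8 from 133237171 to 133302022 and CA9 on chromosome 9 from 35673856 to 35681159. Of 22 glycolysis genes, 13 were lower and 0 higher (19 and 0 adjusted over the list alone), numbering 8 without HIF1A-null ciclopirox replicate 3 or WT ciclopirox replicate 2. Of 16 histone genes, 6 were higher and 0 lower (8 and 0 adjusted over the list alone), with H3C2 at 2.30 ± 0.38 and H1-4 at 1.71 ± 0.34, and 3 were higher without HIF1A-null ciclopirox replicate 3 or WT ciclopirox replicate 2. Of 8 metal response genes, 4 were lower and 0 higher (5 and 1 adjusted over the list alone), with MT1X at -3.69 ± 0.71, and 2 were lower without WT ciclopirox replicate 2. Relative to HIF1A-null DMSO the median of this list was 0.39, 0.78 and 0.36 in the HIF1A-null ciclopirox libraries, and WT ciclopirox replicate 3, at 0.31, was no higher than these. Camera called HIF targets (adjusted p = 6.04e-87 and, with an estimated correlation, adjusted p = 2.37e-06), glycolysis (adjusted p = 1.61e-37 and, with an estimated correlation, adjusted p = 0.000113) and histones (adjusted p = 8.69e-12 and, with an estimated correlation, adjusted p = 0.0419). The metal response list passed with the preset correlation (adjusted p = 3.39e-05, and adjusted p = 0.13 with an estimated correlation). In the planned interaction 29 HIF targets rose less or fell in HIF1A-null cells and 0 the reverse (30 and 1 adjusted over the list alone), with INSIG2, a brake on sterol synthesis, at -4.62 ± 0.48 and the DNA demethylase gene TET1 at -4.68 ± 0.52 (camera adjusted p = 9.38e-15, and adjusted p = 0.17 with an estimated correlation). Such interaction values also hold the genotype difference in DMSO. Neither gene was among the 12 strongest lower changes that the naming rule gave in the direct comparison. In this interaction 1 HIF target was higher without HIF1A-null ciclopirox replicate 3 or WT ciclopirox replicate 1. By edgeR, 286 probes differed between genotypes under ciclopirox, 76 higher and 210 lower. DESeq2 called 533, the fit of only the compared groups 78, voom 442 and the quality axis fit 573. The count was 180 without HIF1A-null ciclopirox replicate 3, 180 without WT ciclopirox replicate 1 and 164 without WT ciclopirox replicate 2. The interaction called 5863 probes, 2925 higher and 2938 lower, 1455 with WT DMSO replicates 1 and 2 left out and 1473 with the quality axis as a covariate.

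**Figure D3:**
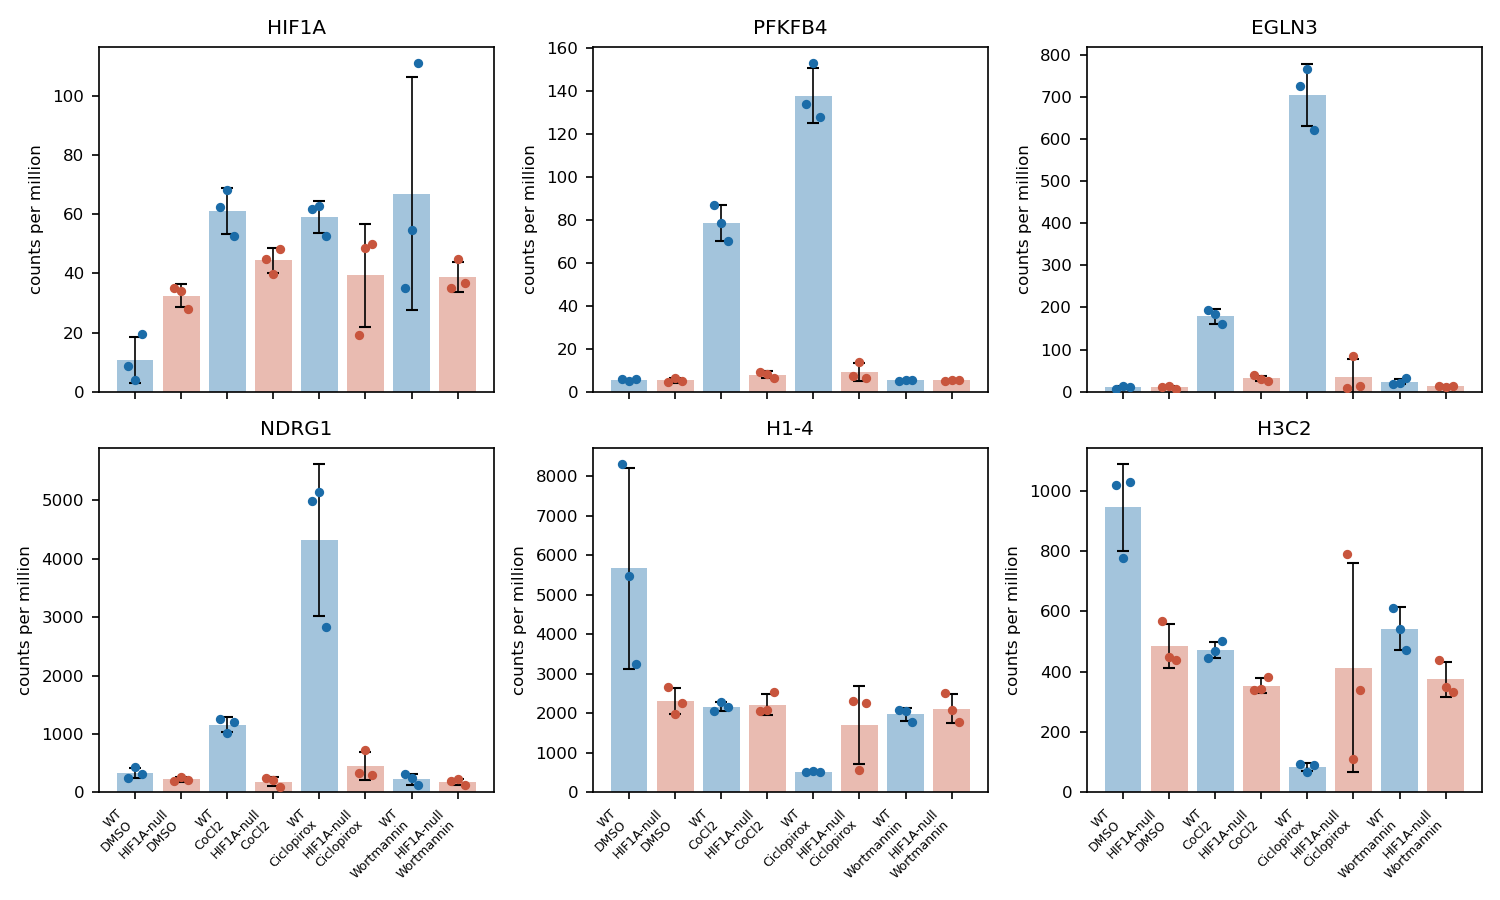
CPM of 6 genes by group, with EGLN3 by probe EGLN3_88861 and NDRG1 by probe NDRG1_21187. Bars give the mean, error bars the SD of 3 libraries and points the libraries. PFKFB4 reaches 138 ± 13.0 in WT ciclopirox libraries and 9.19 ± 4.00 in HIF1A-null ciclopirox libraries, and H1-4 is at 574 in HIF1A-null ciclopirox replicate 2.

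Wortmannin served as an exposure that blocks a kinase rather than mimicking hypoxia. In WT cells 16 of 26 genes of G2 and mitosis were higher than with DMSO and 3 lower (18 and 4 adjusted over the list alone, camera adjusted p = 0.0086, and adjusted p = 0.998 with an estimated correlation). Camera also called that list higher against WT DMSO in WT CoCl2 and in HIF1A-null DMSO (both adjusted p = 0.998 with an estimated correlation), but not in WT ciclopirox, with 9 higher and 6 lower (9 and 6 adjusted over the list alone, adjusted p = 0.795). Its median relative to HIF1A-null DMSO was -0.95, -1.05 and -0.71 in the 3 WT DMSO libraries. HIF targets gave 12 higher and 7 lower of 44 (12 and 7 adjusted over the list alone, median 0.28, camera adjusted p = 0.574), with 3 lower without WT DMSO replicate 2 or WT wortmannin replicate 3. Genes regulated by FOXO factors, which the kinase pathway restrains, gave 9 higher and 6 lower of 26 (9 and 6 adjusted over the list alone, camera adjusted p = 0.705), with 6 and 3 without WT DMSO replicate 2 and 4 and 3 without WT wortmannin replicate 3. LTN1, a ribosome-quality-control ligase gene, was higher by 3.13 ± 0.38 than with DMSO in WT cells and CALM3 lower by -4.65 ± 0.56. HIF1A-null DMSO libraries, which had no wortmannin, differed alike from WT DMSO, by 3.41 ± 0.39 for LTN1 and -4.83 ± 0.57 for CALM3. These 2 values therefore do not show a response to wortmannin. The WT DMSO libraries held 9.07% to 12.35% of counts in 50 probes. In total, edgeR called 6979 probes, 3738 higher and 3241 lower, 139 with WT DMSO replicates 1 and 2 left out, 3496 with only the compared groups in the fit and 1896 with the quality axis as a covariate.

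In HIF1A-null cells wortmannin changed 0 probes by edgeR's quasi-likelihood test, with 452 at an unadjusted p below 0.05, 0 by DESeq2 and 466 by limma voom with sample weights. Immediate early genes had a median of -0.31 with 3 of 24 positive (0 passing over all genes and 0 adjusted over the list alone, camera adjusted p = 0.000859, and adjusted p = 0.485 with an estimated correlation). Genes of G2 and mitosis had a median of 0.28 with 21 of 26 positive (0 passing either way, camera adjusted p = 0.00908, and adjusted p = 0.998 with an estimated correlation), a call lost without HIF1A-null wortmannin replicate 2 (adjusted p = 0.332) and without HIF1A-null DMSO replicate 2. In the direct comparison of genotypes under wortmannin, added after seeing the data, 0 of 44 HIF targets passed (0 higher and 1 lower adjusted over the list alone, median -0.14, camera adjusted p = 0.59). Without WT wortmannin replicate 3, 2 HIF targets were higher and 2 lower. CA9 differed by -3.03 ± 0.77 and did not pass, but did by DESeq2 and without WT wortmannin replicate 3. Of 14 luminal markers, 0 passed over all genes and 9 were lower adjusted over the list alone, with a median of -0.89 (camera adjusted p = 4.26e-10, and adjusted p = 0.16 with an estimated correlation), and 4 were lower over all genes without WT wortmannin replicate 3. Of 8 fibroblast markers, 0 passed over all genes and 3 were higher adjusted over the list alone, with a median of 0.70 (camera adjusted p = 3.39e-05, and adjusted p = 0.137 with an estimated correlation), a call lost without WT wortmannin replicate 3 (adjusted p = 0.0663), where 2 were higher over all genes, as was 1 without HIF1A-null wortmannin replicate 2. By edgeR, 1 probe differed, that of the collagenase gene MMP13 (log2 2.30 ± 0.37), named here after its value was seen, while 2011 had an unadjusted p below 0.05, DESeq2 called 168 and voom with sample weights 6055. With only the compared groups in the fit 0 were called, and 55 with the quality axis as a covariate. The count was 0 without HIF1A-null wortmannin replicate 1 or 3 and without WT wortmannin replicate 1 or 2, 5 without HIF1A-null wortmannin replicate 2 and 630 without WT wortmannin replicate 3. In the wortmannin interaction 47.7% of calls were higher with TMM factors and 55.9% with DESeq2 size factors, so the larger direction depended on scaling. The interaction called 1220 probes, 582 higher and 638 lower, of which CALM3 had a value of 4.45 ± 0.74. It called 205, 150 and 3797 without WT DMSO replicates 1, 2 and 3, 198, 196 and 602 without those of HIF1A-null DMSO, 2511, 687 and 216 without those of WT wortmannin, and 375, 388 and 227 without those of HIF1A-null wortmannin. It called 0 with WT DMSO replicates 1 and 2 left out, 3 with only the compared groups in the fit, 612 with the quality axis as a covariate, 2396 by DESeq2 and 2944 by voom.

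The changes with CoCl2 and with ciclopirox in WT cells were set side by side. The same probe changed in the same direction in 7689 cases, 3978 higher and 3711 lower, and in opposite directions in 11. These were 86.6% of the CoCl2 calls and 88.0% of the ciclopirox calls. Independent lists of these sizes would share 1349.2 higher and 1196.1 lower probes. Both comparisons used the same 3 WT DMSO libraries, as did genotype in DMSO, which shares neither exposure. It changed 6792 probes in the same direction as CoCl2 (85.1% of its calls, correlation of log2 changes 0.88, covariance 1.664), 6839 in the same direction as ciclopirox (85.7%, 0.88 and 1.627) and 6248 in the same direction as wortmannin (78.3%, 0.92 and 1.359). In 20 simulated draws of unchanged groups against those controls, the highest overlap was 0, the median correlation of log2 changes across probes was 0.56 against an observed 0.94, and the median covariance was 0.125 against 1.945. In these draws WT DMSO did not differ from either exposed group, and no variation was shared by the genes of a library. They therefore give no value of chance for the real libraries. Probes are not independent replicates, and the 3 controls are too few to split. Of the 7689 probes, 5746 were called in the same direction in all 4 comparisons with WT DMSO. Most of the overlap was thus also seen without CoCl2 or ciclopirox, and does not by itself show a response that these exposures share. Between genotypes within CoCl2 and within ciclopirox, which share no library, 95 probes differed in the same direction, 10 higher and 85 lower in HIF1A-null cells, where independent lists would share 0.4 and 2.8. The 85 lower probes included those of PFKFB4, CA9, EGLN3, NDRG1, HK2 and ENO2. Both comparisons set the same knockout pool against the same WT line, so genotype differences that do not depend on exposure enter both. The excess over independent lists therefore does not by itself show a response that the exposures share. CoCl2 changed 1233 probes in the same direction in both genotypes (2166 by DESeq2), which was 0 without HIF1A-null CoCl2 replicate 3 or HIF1A-null DMSO replicate 2, 13 without HIF1A-null DMSO replicate 3, 230 without HIF1A-null CoCl2 replicate 2, 572 without HIF1A-null DMSO replicate 1 and 776 without HIF1A-null CoCl2 replicate 1. For ciclopirox and for wortmannin 0 probes were called in both genotypes, and 3 for ciclopirox without HIF1A-null ciclopirox replicate 1.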

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

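The comparisons of probe pairs of 1 gene, the median under wortmannin, the use of the ATF4 list for the HIF targets and the test of the histone list in the interaction were chosen after the results were seen, as were the comparisons of genotypes within 1 exposure.

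The interaction test called 2832 probes for CoCl2, 5863 for ciclopirox and 1220 for wortmannin. It subtracts the genotype difference in DMSO, so the departure of the WT DMSO libraries enters every interaction count. Genotypes differed at 7983 probes in DMSO, but at 292, 286 and 1 under CoCl2, ciclopirox and wortmannin. The interaction counts therefore do not by themselves show a response to exposure that depends on genotype. Among the genes named above the calls included PFKFB4 for CoCl2 (log2 -3.23), INSIG2 (-4.62) and TET1 (-4.68) for ciclopirox, and CALM3 (4.45) for wortmannin. CALM3 was also at 4.50 and 5.26 in the CoCl2 and ciclopirox interactions. Chance was not excluded for any of the interaction counts. Of 100 splits of the 12 libraries, 12 called as many probes as the 2832 of the real split for CoCl2 (highest other 7473), 5 as many as the 5863 for ciclopirox (highest other 6944) and 12 as many as the 1220 for wortmannin (highest other 7779). The 11, 4 and 11 other splits as large all kept the genotypes of the DMSO libraries. Of 12 splits that kept them, the real split included, 12, 5 and 12 called as many as the real split. Splits that did not keep them called at most 35, 59 and 1. Splits that kept them also kept the genotype difference in DMSO inside the interaction, so large counts followed from that difference. The splits therefore cannot tell a departure of the WT DMSO libraries from a genotype difference in DMSO.

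Contrasts of 2 groups have 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 7983 and 0 for genotype in DMSO, 8874 and 0, 8740 and 0, and 6979 and 17 for CoCl2, ciclopirox and wortmannin in WT cells, and 1669 and 0, 0 and 0, and 0 and 0 in HIF1A-null cells. Between genotypes they were 292 and 0 under CoCl2, 286 and 0 under ciclopirox and 1 and 0 under wortmannin.

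Each of the 4 comparisons of 2 groups with WT DMSO called 6979 probes or more. Of 676 pairs of probes for 1 gene that were both called between genotypes in DMSO, 141 went opposite ways (20.9%, exact 95% interval 17.9 to 24.1), against 0 of 91 pairs (upper limit 4.0%) in 3 comparisons without WT DMSO, which made fewer calls. Among the 1669 strongest of these calls the share was 2.0% (1 of 49, interval 0.1 to 10.9), so neither RNA or assay quality of the WT DMSO libraries nor a gene-level expression difference in these cells as the whole cause was excluded. With every library thinned to 3842482 counts 7599 probes were called against 7983, and 7378 were called in the same direction in both, which argues against lower depth. Quality and expression stay open, because WT cells in DMSO were measured in these libraries only.

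HIF targets were lower in HIF1A-null than in WT cells under CoCl2 and under ciclopirox. These comparisons use no WT DMSO library, and the list passed with an estimated correlation (adjusted p = 0.000499 and 2.37e-06). With the library quality axis as a covariate the median log2 difference was -1.16 under CoCl2 (from -1.31) and -1.61 under ciclopirox (from -1.70), which argues against that axis as the whole cause. Under wortmannin the median was -0.14, and for CoCl2 the values are consistent with loss of HIF1A function as a hypothesis found and tested on the same data, while other differences between the knockout pool and the WT cells stay open, such as fibroblast markers under CoCl2 (median 0.54, adjusted p = 0.0026, and adjusted p = 0.246 with an estimated correlation). For ciclopirox it stays open whether HIF1A-null replicates 1 and 3 were exposed like replicate 2 (HIF target medians relative to HIF1A-null DMSO -0.09 and 0.35 against 0.86), although replicate 2 itself was below the 2.23 or more in WT. Of the 21 libraries outside WT DMSO, HIF1A-null ciclopirox replicate 1 had the lowest first-component score (-54.7) and the highest share of counts in 50 probes (8.25%). Its library quality therefore stays open too. The ATF4 medians did not decide the question of exposure. In HIF1A-null ciclopirox replicate 1 the median of 0.06 lay within the range of 6 HIF1A-null DMSO and wortmannin libraries. In replicate 3 the median of 0.96 lay above their highest, 0.53. A WT ciclopirox library, at -0.13, also lay within that range, so a low median does not mark a lack of exposure. The ATF4 list also shares VLDLR, STC2 and DDIT4 with the HIF target list.

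Under ciclopirox 10 of 16 histone genes fell in WT cells (camera adjusted p = 0.00048, and adjusted p = 0.62 with an estimated correlation), while the list median relative to HIF1A-null DMSO was -0.19, -1.15 and -0.04 in HIF1A-null ciclopirox replicates 1, 2 and 3. With the library quality axis as a covariate the median difference between genotypes under ciclopirox was 0.82 (from 0.89), which argues against that axis as the whole cause. That HIF1A-null ciclopirox replicates 1 and 3 were not effectively exposed was not decided, since relative to HIF1A-null DMSO their ATF4 list medians of 0.06 and 0.96 lay within and above the range of -0.37 to 0.53 in 6 HIF1A-null DMSO and wortmannin libraries, and a WT ciclopirox library was as low as -0.13. The histone list in the interaction had an adjusted p = 0.989 with an estimated correlation, so a dependence of the histone response on genotype also stays open.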

How the results depend on the processing

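The library quality axis as a covariate, limma voom with sample weights, WT DMSO libraries left out, leaving out a library in list tests and all settings for the 3 comparisons of genotypes within an exposure were chosen after seeing the data. Counts are of probes called. Where a count moved by over 1.5 times it is given here, and the cause was not tested unless stated. With the quality axis as a covariate, genotype in DMSO gave 4018, CoCl2, ciclopirox and wortmannin in WT cells 2151, 2719 and 1896, CoCl2 in HIF1A-null cells 0, the ciclopirox and wortmannin interactions 1473 and 612, and genotypes under ciclopirox and wortmannin 573 and 55. Without WT DMSO replicates 1 and 2, which leaves 1 WT DMSO library assumed to vary like the other groups, genotype in DMSO gave 2153, CoCl2, ciclopirox and wortmannin in WT cells 4912, 4394 and 139, the interactions 39, 1455 and 0, and genotypes under wortmannin 10, as also without all WT DMSO libraries. With only the compared groups in the fit, wortmannin in WT cells gave 3496, CoCl2 in HIF1A-null cells 4672, the wortmannin interaction 3, and genotypes under CoCl2, ciclopirox and wortmannin 2160, 78 and 0. DESeq2 called 2970 for CoCl2 in HIF1A-null cells, 2396 for the wortmannin interaction, 687, 533 and 168 between genotypes, and 2166 for CoCl2 in both genotypes. Voom called 7226, 57 and 466 in HIF1A-null cells, 4734 and 2944 for the CoCl2 and wortmannin interactions, and 4017, 442 and 6055 between genotypes. Between genotypes under wortmannin 17 were called with no filter and 7 with probes summed per gene. With an estimated correlation 0 of the 37 list calls among 260 tests passed, and 5 of the 21 among 78. Fry, which asks whether a list moves one way rather than whether it differs from other genes, ended 17 of the 37 and 5 of the 21, among them all 13 for ciclopirox in HIF1A-null cells, and passed 34 and 16 tests in all. With 1 library left out, the counts ranged from 6546 to 8565 for genotype in DMSO, and in WT cells from 7915 to 9328 for CoCl2, 7609 to 9164 for ciclopirox and 4732 to 7839 for wortmannin. In HIF1A-null cells they ranged from 0 to 1140, 0 to 4 and 0 to 0, for the interactions from 1676 to 4762, 4145 to 6742 and 150 to 3797, and between genotypes from 86 to 184, 164 to 376 and 0 to 630. The overlap of CoCl2 and ciclopirox in WT cells ranged from 6578 to 8218, that of genotypes in CoCl2 from 0 to 1210, in ciclopirox from 0 to 3 and in wortmannin from 0 to 0, and the list calls from 32 to 40 and from 18 to 25. In simulated CoCl2 data for WT cells, 66.7% of genes changed 4-fold and 1.5% of those changed 1.5-fold were recovered. The simulation made 70 calls against 8874 in the real comparison, so its adjusted threshold was stricter. It also held no variation shared by the genes of a library. These shares therefore give no detection limit for the real data. Under DESeq2 size factors within edgeR 0 of these counts moved by over 1.5 times. Of the 64 log2 values of named genes, 0 calls changed direction, DESeq2 size factors and the block ended 0 calls, DESeq2 added 2, and calls were lost 43 times and gained 2 times with a library left out.

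The replicate number as a block gave 8024 for genotype in DMSO, 8961, 8788 and 7079 in WT cells, 2275, 0 and 0 in HIF1A-null cells, 3103, 6056 and 1627 for the interactions and 333, 308 and 4 between genotypes, with 39 and 22 list calls. Not every pair of libraries with the same number deviated together: of 84 pairs 24 had a correlation over 0.1. In 2 of 28 pairs of groups all 3 did, and the range was -0.44 to 0.65 with a median of 0.00. Of the 24 libraries 13 correlated best with their own number. These values do not exclude a batch shared by some libraries of the same number. The number was not taken as a pairing because no label states one.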

Other observations

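The comparisons of genotypes within 1 exposure and the list tests with a library left out were chosen after the results were seen, and so was the naming of GDF15 and LUM together with FMN1 and MYOD1 from the many genes that the rule allows.

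In HIF1A-null cells with ciclopirox 0 single probes passed edgeR's quasi-likelihood test (264 at an unadjusted p below 0.05, DESeq2 0, limma voom 57), while 13 gene lists passed camera at the preset correlation, 0 of them with an estimated correlation or by fry. Of 28 genes of sterol and fatty acid synthesis 26 had positive log2 values, with a median of 0.40 (camera adjusted p = 1.05e-07, and adjusted p = 0.275 with an estimated correlation). Of 22 glycolysis genes 0 passed (1 higher and 0 lower adjusted over the list alone), with a median of 0.40 (adjusted p = 1.04e-08, and adjusted p = 0.254 with an estimated correlation). All 18 NRF2 genes were positive with a median of 0.27 (adjusted p = 0.000555, and adjusted p = 0.359 with an estimated correlation), as were 21 of 25 p53 targets with 0.30 (adjusted p = 0.000218, and adjusted p = 0.223 with an estimated correlation) and 24 of 28 genes of MYC and ribosome biogenesis with 0.26 (adjusted p = 0.000514, and adjusted p = 0.747 with an estimated correlation). Of 18 interferon-stimulated genes 5 were positive, with a median of -0.25 (adjusted p = 0.00137, and adjusted p = 0.747 with an estimated correlation). In the sterol, NRF2, p53, MYC and interferon lists 0 members passed over all probes and 0 adjusted over the list alone. The glycolysis call was lost without HIF1A-null ciclopirox replicate 2 (adjusted p = 0.218), and that of MYC without that replicate (adjusted p = 0.155) or HIF1A-null DMSO replicate 1. The sterol, NRF2 and interferon calls were lost without HIF1A-null ciclopirox replicate 3 (adjusted p = 0.0718, 0.063 and 0.368). Lists for fibroblasts, metal response, E2F and autophagy also passed (median -0.39, 0.54, -0.08 and 0.12, adjusted p = 0.0065, 0.0245, 0.0271 and 0.0395, and adjusted p = 0.62, 0.73, 0.716 and 0.947 with an estimated correlation). In these 4 lists too 0 members passed over all probes and 0 adjusted over the list alone. All 4 calls were lost without HIF1A-null ciclopirox replicate 3, those for fibroblasts, metal response and autophagy without replicate 2, and those for metal response and E2F without replicate 1. With 1 library left out their highest adjusted p was 0.197, 0.442, 0.884 and 0.992, and those for metal response and autophagy were lost without HIF1A-null DMSO replicate 2 or 3 and that for E2F without HIF1A-null DMSO replicate 1.

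Fibroblast markers were also compared between genotypes under the other exposures. In CoCl2 2 of 8 were higher and 0 lower in HIF1A-null cells (3 and 0 adjusted over the list alone, median 0.54, adjusted p = 0.0026, and adjusted p = 0.246 with an estimated correlation), and in ciclopirox 1 and 0 (3 and 0 adjusted over the list alone, median 0.66, adjusted p = 0.000264, and adjusted p = 0.18 with an estimated correlation). The call in CoCl2 was lost without HIF1A-null CoCl2 replicate 1 (adjusted p = 0.0562). The 2 members became 0 without WT CoCl2 replicate 1 or 2 and 1 without WT CoCl2 replicate 3 or HIF1A-null CoCl2 replicate 1, and the 1 in ciclopirox became 0 without HIF1A-null ciclopirox replicate 1 or 3 or any 1 WT ciclopirox library. In HIF1A-null cells with CoCl2 the same list had 0 members higher and 3 lower than with DMSO (1 and 6 adjusted over the list alone, median -0.78, adjusted p = 0.0256, and adjusted p = 0.747 with an estimated correlation), a call lost without HIF1A-null CoCl2 replicate 3 (adjusted p = 0.102) or HIF1A-null DMSO replicate 1. The 3 became 0 without HIF1A-null CoCl2 replicate 2 or 3 or HIF1A-null DMSO replicate 2 or 3. LUM, a matrix proteoglycan gene of this list, was at 25.1 ± 15.9 CPM in HIF1A-null DMSO and 57.8 ± 11.5 in HIF1A-null CoCl2 libraries, against 1.58 ± 1.88 and 10.0 ± 2.82 in WT. Its difference in CoCl2, 2.53 ± 0.52, did not pass without WT CoCl2 replicate 1 or 2. FMN1, a formin gene, was at 22.3 ± 9.58, 35.7 ± 17.4, 24.2 ± 14.8 and 32.0 ± 8.95 CPM in HIF1A-null DMSO, CoCl2, ciclopirox and wortmannin libraries, against 1.76 ± 2.49, 4.17 ± 0.689, 4.73 ± 0.561 and 6.18 ± 0.982 in WT. By edgeR it was higher in HIF1A-null cells by 3.38 ± 0.61 in DMSO, 3.10 ± 0.55 in CoCl2 and 2.35 ± 0.53 in ciclopirox. The difference in DMSO rested on 0, 2 and 29 counts in WT DMSO replicates 1, 2 and 3, and its log2 value was over 1.5 times as large without replicate 3. The difference in ciclopirox did not pass without HIF1A-null ciclopirox replicate 3 or any 1 of the WT ciclopirox libraries. In wortmannin FMN1 differed by 2.36 ± 0.53 and did not pass (adjusted p = 0.0959), but did by DESeq2 and without WT wortmannin replicate 3. MYOD1, a muscle regulator gene, was at 7.95 ± 1.80 CPM in WT CoCl2 and 4.89 ± 1.02 in WT ciclopirox libraries, and at 0.349 ± 0.494 or less in the other 6 groups.

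Of 25 p53 targets, 7 were higher and 11 lower in HIF1A-null than in WT cells with DMSO (7 and 11 adjusted over the list alone, median -0.37, camera adjusted p = 0.775). GDF15, a stress-induced cytokine gene in this list, was at 345 ± 3.93 CPM in WT ciclopirox libraries and 166 ± 65.0 in HIF1A-null ciclopirox libraries, a difference of -1.05 ± 0.25 that did not pass without HIF1A-null ciclopirox replicate 1 or 3 or any 1 WT ciclopirox library. With CoCl2 in HIF1A-null cells 0 p53 targets were higher and 3 lower (1 and 12 adjusted over the list alone, median -0.58, adjusted p = 0.0141, and adjusted p = 0.399 with an estimated correlation), and 0 were lower without HIF1A-null CoCl2 replicate 3 or HIF1A-null DMSO replicate 2 or 3. Between genotypes under CoCl2, 0 were higher and 1 lower (0 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.0168, and adjusted p = 0.229 with an estimated correlation), lost without HIF1A-null CoCl2 replicate 3 (adjusted p = 0.0523), and 0 were lower without that library or any 1 WT CoCl2 library. Of 11 HIF pathway components, 0 were higher and 2 lower in HIF1A-null cells under CoCl2 (0 and 3 adjusted over the list alone, median -0.40, adjusted p = 0.00528, and adjusted p = 0.18 with an estimated correlation), and 1 was lower without HIF1A-null CoCl2 replicate 3. Under ciclopirox 0 were higher and 2 lower (0 and 2 adjusted over the list alone, adjusted p = 0.00913, and adjusted p = 0.229 with an estimated correlation), where the median was 0.15 and the mean and the test were negative. In the CoCl2 interaction 0 were higher and 3 lower (0 and 3 adjusted over the list alone, median -0.76, adjusted p = 0.0337, and adjusted p = 0.55 with an estimated correlation), lost without HIF1A-null CoCl2 replicate 3 (adjusted p = 0.0788) or WT DMSO replicate 1. The 3 became 1 without WT DMSO replicate 1 and 5 without WT DMSO replicate 3.

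Other list results stood as follows. Glycolysis in the interactions had 1 member higher and 9 lower for CoCl2 (1 and 11 adjusted over the list alone, median -1.13, adjusted p = 6.96e-05, and adjusted p = 0.485 with an estimated correlation) and 0 and 13 for ciclopirox (0 and 13 adjusted over the list alone, median -1.66, adjusted p = 3.06e-05, and adjusted p = 0.399 with an estimated correlation). The 1 higher for CoCl2 became 0 without any 1 of the libraries compared other than HIF1A-null CoCl2 replicate 1 and WT DMSO replicate 3, and for ciclopirox 1 was higher without HIF1A-null ciclopirox replicate 3 or WT DMSO replicate 3. Histones in the ciclopirox interaction had 9 higher and 0 lower (9 and 0 adjusted over the list alone, median 1.01, adjusted p = 0.0133, and adjusted p = 0.989 with an estimated correlation), lost without HIF1A-null ciclopirox replicate 3 (adjusted p = 0.063) or WT DMSO replicate 3, and 2 were lower without the latter. Luminal markers in the CoCl2 interaction had 3 higher and 0 lower (3 and 0 adjusted over the list alone, median 0.77, adjusted p = 0.0245, and adjusted p = 0.998 with an estimated correlation), lost without HIF1A-null CoCl2 replicate 3 (adjusted p = 0.138), HIF1A-null DMSO replicate 3 or WT DMSO replicate 3. Between genotypes under CoCl2, heat shock genes had 1 higher and 0 lower (3 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.00216, and adjusted p = 0.231 with an estimated correlation) and FOXO targets 0 and 1 (0 and 3 adjusted over the list alone, median -0.30, adjusted p = 0.00718, and adjusted p = 0.214 with an estimated correlation). The heat shock gene did not pass without HIF1A-null CoCl2 replicate 3 or any 1 WT CoCl2 library, nor did the FOXO target without HIF1A-null CoCl2 replicate 3 or WT CoCl2 replicate 2 or 3. Under ciclopirox, estrogen receptor targets had 0 higher and 2 lower (0 and 7 adjusted over the list alone, median -0.58, adjusted p = 4.5e-05, and adjusted p = 0.229 with an estimated correlation) and luminal markers 0 and 1 (0 and 1 adjusted over the list alone, median -0.60, adjusted p = 9.93e-05, and adjusted p = 0.422 with an estimated correlation). The 2 estrogen receptor targets became 0, 5 and 1 without HIF1A-null ciclopirox replicates 1, 2 and 3, and 1 and 0 without WT ciclopirox replicates 2 and 3. The luminal marker did not pass without any 1 of the 6 libraries other than HIF1A-null ciclopirox replicate 2. Also under ciclopirox the medians of sterol genes, genes of G2 and mitosis and genes of MYC and ribosome biogenesis were 0.35, 0.33 and 0.31 with 0 members passing over all probes and 0 adjusted over the list alone (adjusted p = 0.00216, 5e-04 and 0.0113, and adjusted p = 0.422, 0.426 and 0.579 with an estimated correlation), while 2 sterol genes were higher without HIF1A-null ciclopirox replicate 1 and 1 gene of G2 and mitosis without its replicate 2. The luminal, sterol and G2 calls under ciclopirox were lost without HIF1A-null ciclopirox replicate 3 (adjusted p = 0.0762, 0.197 and 0.215), and the MYC call without HIF1A-null ciclopirox replicate 2 (adjusted p = 0.245) or WT ciclopirox replicate 3. Under wortmannin 0 estrogen receptor targets passed (0 higher and 2 lower adjusted over the list alone, median -0.44, adjusted p = 0.000264, and adjusted p = 0.308 with an estimated correlation), a call lost without WT wortmannin replicate 3 (adjusted p = 0.0631), where 3 were lower over all probes.

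Lists for iron handling, the ER unfolded protein response, mitochondrial respiration, NF-kB, basal and mesenchymal markers and blood cell markers were not called by camera in any of the 13 contrasts, their lowest adjusted p being 0.539, 0.154, 0.527, 0.255, 0.131 and 0.182. Single members still passed: between genotypes in DMSO, 6 of 16 iron genes were higher and 3 lower (7 and 3 adjusted over the list alone). The autophagy list was called for ciclopirox in HIF1A-null cells at the preset correlation, but not with an estimated correlation or by fry. Of its 25 genes, 10 were higher between genotypes in DMSO and 5 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.375).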
